A study of Mus musculus with 12 samples.

How the data were processed

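Total RNA was extracted from mouse ovaries of 12 animals at P0 and P7, per the labels' protocols, and hybridised to Illumina BeadChips with 45281 probes. The labels give the tissue as oocytes, but the protocols describe gonads and ovaries, and the text follows the protocols. Groups (genotype and age) and replicate numbers came from the sample titles, with 3 biological replicates in each of 4 groups. The animals were of a mixed background of several strains, per the labels.

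The arrays were read with GenomeStudio 2011.1, per the submitters' processing notes. The deposited values are scores: on each array the authors' values have a mean of 0 and an SD of 1 over all probes, as tested on the values. The P0 columns carry up to 6 decimals and the P7 columns 2, so the ages were processed in separate runs or exported differently. The column medians were −0.389, −0.386 and −0.406 in wild type and −0.362, −0.321 and −0.345 in knockout at P0, and −0.49, −0.45 and −0.49 in wild type and −0.49, −0.5 and −0.48 in knockout at P7. Centring and scaling are therefore per array, and a higher score is a brighter probe. Whether a log was taken before the scores were made, its base and the background correction are not given in the sources used here, so no fold change is given. A further 48 columns, 24 of signal or score and 24 of detection p, carry names that give a genotype and an animal code but match no single sample's labels, and they were not used. The 12 score columns among them hold the same values as the 12 deposited columns used here (all 45281 probes), but no sample was assigned to a column by its values, so their detection p-values and signals were left out.

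Scores were quantile-normalized over the 12 arrays. In place of those detection p-values, background was set per array as the 95th percentile of 1523 probes for olfactory, vomeronasal and trace amine receptors, genes taken to be silent in ovary. Probes above it on at least 3 of the 12 arrays were kept (23144 probes, 19532 of them with a gene name). Of all probes 34885 had 1 gene symbol, 18 had several and 10378 had none in the platform annotation used here, probes with several were not named, and 99.8% of gene IDs were found in the RefSeq table of assembly GRCm38.p6, which updated symbols. For each gene the probe with the highest mean over all arrays was taken, which left 12215 of 19057 genes with a named probe. Among the called genes, another probe was called the opposite way for 30 at P0 and 21 at P7. Other probes of a called gene can also show no change, which these counts leave out. Where the lower group was not above background on any of its arrays, the difference is given as a bound against the array's background level ("at least"), and none is given where both groups were below it. This was so for the lower group of 575 called genes at P0 and 373 at P7. No level is compared between probes.

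Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) in 1 model of 4 groups with 8 residual degrees of freedom and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, at 0.05. The contrasts were knockout against wild type at P0 and at P7, the difference of these as an interaction, and P7 against P0 in each genotype. An exact permutation test of 3 arrays against 3 cannot go below 0.1, which is why single genes rest on the model. The design written before the data were examined had assumed bead signals on a log2 scale after background correction on control probes; because the values are scores, the same model was fitted to quantile-normalized scores, with receptor probes in place of detection p-values. The gene lists, the rule for named genes, the contrasts and most of the other settings tried were chosen before the data were examined.

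Gene lists (25, with 539 different genes in all) came from textbook knowledge. They were oocyte growth genes, oocyte transcription regulators, pan germ cell, meiotic prophase, primordial germ cell and pluripotency, autophagy, lysosome, p53 target, DNA break signalling and repair, apoptosis, piRNA pathway, PI3K and mTOR signalling, cell proliferation, and immediate early and heat shock genes, and markers of granulosa, theca and steroidogenic, adrenal cortex, stromal and smooth muscle, endothelial, macrophage and leukocyte, erythroid, surface epithelium and oviduct, adipocyte and testis somatic cells, with Y-linked genes as a check of labels. Of the 24 pan germ cell genes listed 12 belong to another list as well, as do 11 of the 21 piRNA genes, 6 of the 30 p53 targets and 5 of the 35 apoptosis genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation beside it. At P0 no list call held with an estimated correlation. At P7 those of the oocyte growth, oocyte regulator, primordial germ cell, lysosome, DNA break, piRNA, proliferation and stromal lists held, and none held for the interaction or for age.

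Named genes were, per knockout comparison, Lhx8, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between genotypes, up to 4 called members of each list with the smallest adjusted p, and a fixed set of oocyte, germ cell, follicle, autophagy and DNA damage genes. For the interaction and for age they were the 5 largest changes in each direction. Of the fixed set, Zp2 and Sycp3 have 1 named probe each, which did not pass the filter. Neighbours of Lhx8 were genes within 5 Mb by the RefSeq table, tested with a two-sided Fisher exact test. Whether the groups could be told apart by chance was checked by other splits of the same arrays.

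The model was tested on simulated data of 12215 genes, with 50 at each size of change and 1 spread per gene shared by both ages. At P0 it recovered 6% of changes of 0.25 z units, 66% of 0.5, 96% of 1 and 100% of 2, and 4.29% of its calls were false. At P7 it recovered 16%, 52%, 94% and 100%, and 6.43% of its calls were false. The simulated spread came from the real arrays, and genes were drawn as if independent. The rates therefore do not test the model at the spread of each age alone. Nor do they show that recovery or false calls differ between P0 and P7.

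Other settings tried were the deposited scores without quantile normalization, no filter on dim probes, the mean over a gene's probes, eBayes without trend or with robust estimation, array weights, the replicate number as a block, fits to the compared arrays alone, leaving out each array in turn, an adjusted p below 0.01, and for lists an estimated correlation. Quantile normalization within each age, median scaling on the receptor probes and the probes above background, a stricter filter (above the 99th percentile of receptor probes on all arrays of a group) and a minimum difference of 0.5 were chosen after seeing the data.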

Results

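Gene expression was measured in ovaries of newborn (P0) and 7-day-old (P7) mice that carried Lhx8 or lacked it. Lhx8 encodes a LIM homeobox transcription factor of oocytes. Each of the 4 groups held 3 animals with 1 Illumina BeadChip array each, and the 12 arrays covered 12215 genes that could be tested. The values are z scores, so every array has a mean of 0 and an SD of 1 over its probes. Changes are given as differences in z units after quantile normalization, knockout minus wild type unless stated, with the SE of the limma fit and n = 3 animals per group. They are not fold changes, because it is unknown whether a log was taken before the scores were made. A gene is said to rise, fall or change where its adjusted p in limma was below 0.05.

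The arrays separated first by age and then by genotype. The first principal component held 44.7% of the variance and parted the ages, and the second held 31.0% and parted the genotypes. Arrays of 1 group correlated with r from 0.979 to 0.994, those of the same age but the other genotype from 0.939 to 0.973, and those of different ages from 0.809 to 0.929. The share of probes above background was 35.1% ± 1.61 (SD, n = 3) in wild type and 30.2% ± 1.59 in knockout at P0, and 49.4% ± 0.99 and 47.5% ± 1.43 at P7. The number of arrays limits the precision of every value.

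Lhx8 itself was lower in all 6 knockout arrays than in every wild-type array of its age. At P0 its score fell from 1.30 ± 0.38 (SD, n = 3) to 0.25 ± 0.06, a difference of −1.05 ± 0.15 (SE, limma adjusted p = 0.000218). At P7 it fell from 0.97 ± 0.16 to −0.24 ± 0.09, a difference of −1.21 ± 0.15 (adjusted p = 2.1e-05). In array terms, Lhx8 moved from percentile 88.9 to 75.2 at P0 and from 85.8 to 61.5 at P7, and its probe stayed above background on all knockout arrays. Where the probe lies relative to the deleted part of the gene is not given in the sources used here, so the fall does not settle the genotype labels by itself.

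**Figure D1:**
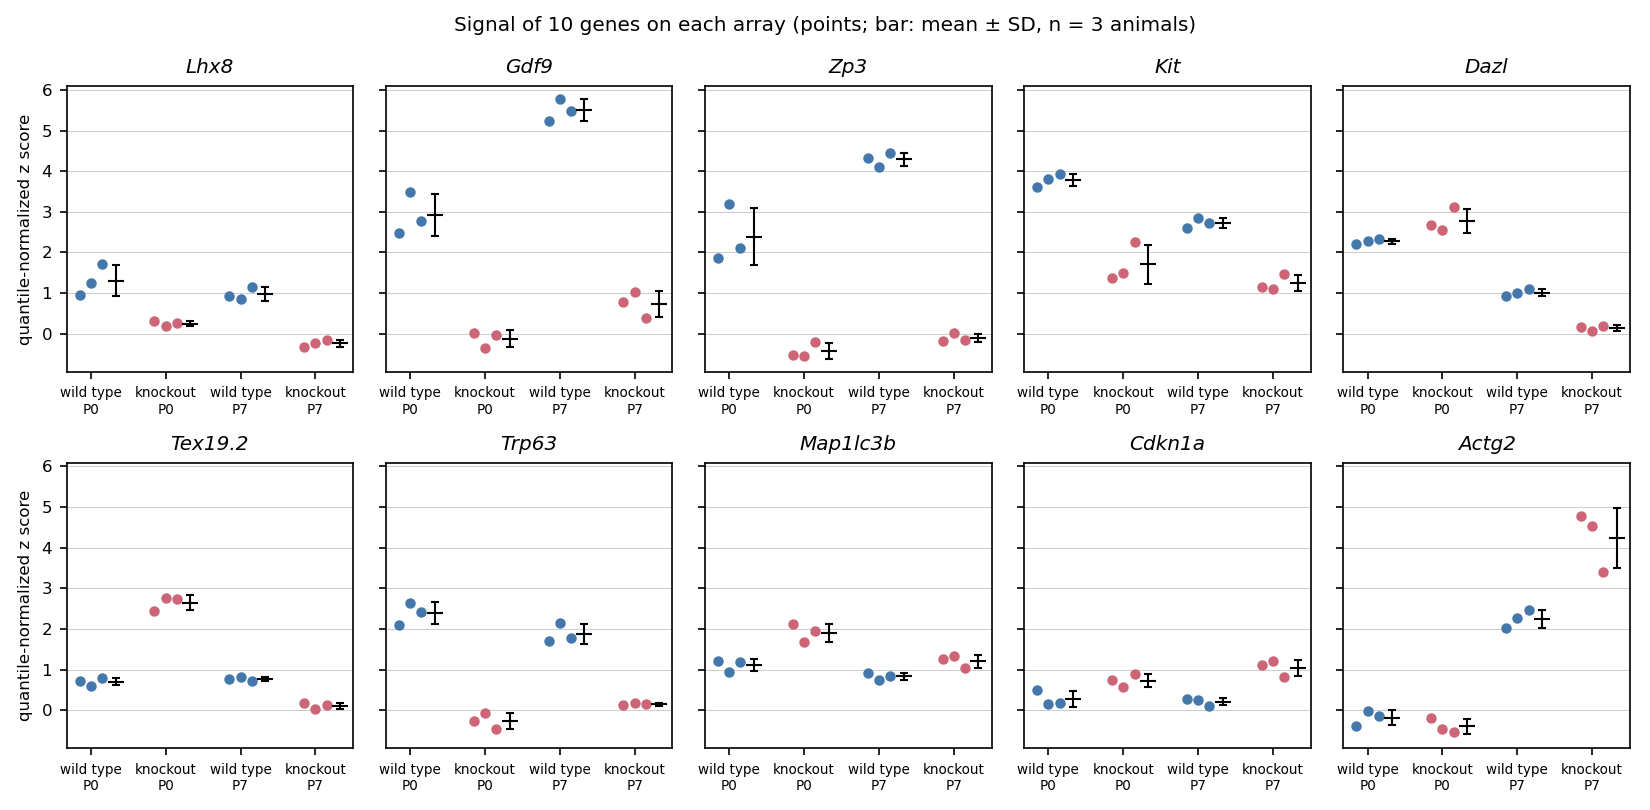
Quantile-normalized z score (vertical axis) of 10 genes on each of the 12 arrays, grouped by genotype and age on the horizontal axis. Each point is 1 animal and the bars give the mean ± SD (n = 3). Lhx8, Gdf9, Zp3 and Kit lie lower in knockout at both ages, whereas Dazl and Tex19.2 lie higher at P0 and lower at P7.

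The P0 comparison asks which transcripts the loss of Lhx8 had altered by birth. Oocyte growth genes, the stores and structures that oocytes build as they grow, were far lower in newborn knockout ovaries. Of the 32 tested, 27 fell and none rose, and their median difference was −1.04. Padi6, needed for the cytoplasmic lattices of the oocyte, differed by −4.75 ± 0.25 (at least −4.41 above background). Nlrp5 (−3.81 ± 0.30) and Ooep (−3.67 ± 0.31), both of the subcortical maternal complex, fell with it, as did the growth factor gene Gdf9 (−3.04 ± 0.22) and the zona pellucida gene Zp3 (−2.82 ± 0.24, at least −2.38). Bmp15 (−0.89 ± 0.16, at least −0.47) and Zp1 (−1.71 ± 0.21, at least −1.13) were low in wild type at this age and lower still in knockout. The list was lower than other genes (camera adjusted p = 8.26e-23; 0 higher and 29 lower when adjusted over the list alone), with adjusted p = 0.145 with an estimated correlation. In 20 of the 32 genes the lower group was not above background, and with each of these at its bound the median was −0.82.

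Some transcription factors of oocyte differentiation, Lhx8 itself among them, also fell. Of 10 oocyte transcription regulators 6 fell and none rose, with a median of −0.46, or −0.21 with the 4 whose lower group was below background at their bound (adjusted p = 0.00134, and adjusted p = 0.134 with an estimated correlation; adjusted over the list alone, 6 fell). Figla, which switches on the zona genes, fell by 1.04 ± 0.16, Nobox differed by −0.48 ± 0.10 (at least −0.12) and Tbpl2 by −0.47 ± 0.06, too close to background for a bound. Sohlh1 (−0.29 ± 0.13, adjusted p = 0.115) and Sohlh2 (−0.05 ± 0.08, adjusted p = 0.68) did not pass the test. Kit, the receptor through which granulosa cells signal to oocytes, fell by 2.08 ± 0.18. With it Pik3cb (−0.60 ± 0.15) and Foxo3 (−0.45 ± 0.13) were the 3 called members, all lower, of 16 PI3K and mTOR signalling genes, whose list did not pass the test (median −0.12, adjusted p = 0.133; the same 3 when adjusted over the list alone).

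Genes common to germ cells moved in both directions at P0. Of 21 pan germ cell genes 8 fell and 4 rose, with a median of −0.20 (adjusted p = 0.0379; 9 lower and 5 higher when adjusted over the list alone; adjusted p = 0.411 with an estimated correlation). The RNA-binding protein gene Elavl2 (−1.93 ± 0.16) and Dppa5a (−2.07 ± 0.20) fell, whereas Dazl (0.51 ± 0.12), Tex19.1 (1.13 ± 0.12) and Taf7l (1.12 ± 0.17) rose. Tex19.2, a close relative of Tex19.1, rose by 1.95 ± 0.10 (adjusted p = 3.24e-08), the largest rise among the 12215 genes. Ddx4, the germ cell RNA helicase, did not pass the test (0.25 ± 0.09, adjusted p = 0.0691), nor did Lin28a (0.09 ± 0.10, adjusted p = 0.569). The call of the pan germ cell list also ended with median scaling, the mean over probes or array weights, and without wild-type replicate 3, knockout replicate 1 or knockout replicate 2.

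Of 19 piRNA pathway genes, which silence transposons in germ cells, 8 fell and none rose (median −0.20, or −0.13 with bounds, adjusted p = 0.0012, with adjusted p = 0.194 with an estimated correlation; adjusted over the list alone, 8 fell and 2 rose). Gtsf1 fell by 1.71 ± 0.16 and Piwil2 by 0.88 ± 0.12. Meiotic prophase genes did not pass the test as a list (24 genes, median −0.06, adjusted p = 0.462; 2 rose and 5 fell, or 2 and 7 adjusted over the list alone), with Spo11, the nuclease of meiotic breaks, higher by 0.64 ± 0.11 and Mnd1 lower (−0.92 ± 0.18). The 15 primordial germ cell and pluripotency genes had a median of −0.01 (adjusted p = 0.116; 2 rose and 6 fell, or 3 and 6 adjusted over the list alone), and among them Tcl1 fell by 2.16 ± 0.17.

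Autophagy genes, the subject named in the title of the series, did not pass the test as a group at P0. Of 36 tested, 4 rose and 4 fell, also when adjusted over the list alone (median −0.01, camera adjusted p = 0.881). Map1lc3b, whose product coats autophagosomes, rose by 0.79 ± 0.12 (adjusted p = 0.00047), and Wdr45 by 0.36 ± 0.10, whereas Atg12 (−0.48 ± 0.09) and Uvrag (−0.39 ± 0.09) fell. The other Uvrag probes, at 0.01 and 0.09, were not called. Becn1 (−0.09 ± 0.12, adjusted p = 0.638) and Sqstm1 (0.16 ± 0.15, adjusted p = 0.477) did not pass the test. Lysosome genes were slightly higher: 9 of 31 rose and 3 fell (median 0.22, adjusted p = 0.0353; 11 and 4 adjusted over the list alone), with adjusted p = 0.194 with an estimated correlation. Lamp2 (0.65 ± 0.11) and Npc2 (0.52 ± 0.10) rose, and the proton pump subunit gene Atp6v1b2 (−0.79 ± 0.10), the channel gene Mcoln1 (−0.75 ± 0.09) and Lamp1 (−0.45 ± 0.10) fell. Another Lamp2 probe was called as well (0.67), and the rest, from 0.04 to 0.23, were not. The lysosome call was also lost with the mean over probes (median 0.14, adjusted p = 0.0756), and without wild-type replicate 2 (adjusted p = 0.0553), wild-type replicate 3 (0.0758) or knockout replicate 1 (0.0873).

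DNA damage was followed by 2 lists at P0, and the difference between them was not tested. None of the 30 DNA break signalling and repair genes rose and 9 fell (median −0.20, adjusted p = 0.00134; 10 lower adjusted over the list alone), with adjusted p = 0.194 with an estimated correlation. Trp63, which guards the genome of oocytes, differed by −2.66 ± 0.15 (at least −2.38), followed by the ubiquitin ligase gene Rnf8 (−1.03 ± 0.13), Rad50 (−0.70 ± 0.10) and Xrcc6 (−0.60 ± 0.09). Another probe of Rnf8, at −0.57, and of Rad50, at −0.12, was not called. In 11 of the 30 the lower group was not above background, and the list median with bounds was −0.04. H2ax did not pass the test (0.14 ± 0.11, adjusted p = 0.383). Of 26 p53 target genes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 0.03 (adjusted p = 0.364). Cdkn1a, the cell cycle inhibitor p21, rose by 0.46 ± 0.13 (adjusted p = 0.0199), Bbc3, a trigger of apoptosis, by 0.59 ± 0.11 and Sesn1 by 0.61 ± 0.11. A further probe of each, at 0.11, 0.15 and −0.14, was not called. The call of Cdkn1a ended on the deposited scores, with median scaling and without wild-type replicate 2, wild-type replicate 3 or knockout replicate 3. The 28 apoptosis genes did not pass the test (median 0.03, adjusted p = 0.704; 2 rose and 3 fell, also adjusted over the list alone).

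Somatic markers at birth were tested by cell type, and differences between the lists were not tested. None of the 21 granulosa cell markers changed at the probe used, also when adjusted over the list alone (median 0.05, adjusted p = 0.399, with 4336 of all genes at an unadjusted p under 0.05), and Foxl2 differed by 0.07 ± 0.09 (adjusted p = 0.625). Another probe of the marker Nr5a2 was called higher (0.41). In 4 of the 21 both genotypes were below background, where a change could not be seen. Endothelial markers were higher, with 4 of 12 rising and none falling (median 0.36, adjusted p = 0.00262; 8 higher adjusted over the list alone), with adjusted p = 0.336 with an estimated correlation, and with Esam at 0.50 ± 0.14. Cell proliferation genes fell in 9 of 25 and rose in none (median −0.20, adjusted p = 0.00153; 12 lower adjusted over the list alone), with adjusted p = 0.194 with an estimated correlation and with Birc5 at −1.04 ± 0.12. Immediate early and heat shock genes, which respond to tissue handling, were higher (3 of 16 rose, or 6 adjusted over the list alone; median 0.23, adjusted p = 0.0124), with adjusted p = 0.358 with an estimated correlation and 0.0758 without wild-type replicate 3; Dusp1 rose by 0.86 ± 0.17. Among macrophage and leukocyte markers 3 of 14 rose (3 adjusted over the list alone; median 0.01, adjusted p = 0.364), led by Laptm5 (0.73 ± 0.14).

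The other cell type lists did not pass the test at P0. Stromal and smooth muscle markers had a median of 0.12 (1 of 13 rose; adjusted p = 0.46), theca and steroidogenic markers −0.02 (1 of 10 rose; adjusted p = 0.907), surface epithelium and oviduct markers −0.02 (1 of 11 fell; adjusted p = 0.956), testis somatic markers 0.25 (2 of 11 rose, 1 fell; adjusted p = 0.364), erythroid markers 0.08 (0 of 4 called; adjusted p = 0.802) and adipocyte markers 0.27 (1 of 3 rose; adjusted p = 0.137). Adjusted over the list alone, these lists gave 0, 1, 0, 2, 0 and 2 higher and 0, 0, 0, 1, 0 and 0 lower. For autophagy genes and theca markers the median and the mean differed in sign, and for surface epithelium markers both were below 0 although the test ranked the list upward. Of the adrenal cortex and Y-linked lists 2 genes each could be tested, too few for a list test, and Cyp11b2 fell by 0.29 ± 0.07 at P0, too close to background for a bound and not called on the deposited scores, whereas Eif2s3y (0.11) and Uty, below background in both genotypes, did not pass the test.

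Further large rises at P0 were in Gadd45g (1.62 ± 0.12), a stress-induced gene, Radx (at least 1.47), the linker histone gene H1f2 (1.46 ± 0.30), the mast cell protease genes Cma1 (1.34 ± 0.33) and Cpa3 (1.26 ± 0.32), which in 1 of the 3 knockout animals lay just above the highest wild-type animal and whose calls ended with array weights, Fabp3 (1.24 ± 0.19) and Pfkl (1.23 ± 0.16). Another Pfkl probe, at 0.04, was not called. Further large falls were in Nlrp14 (−3.55 ± 0.23), Oas1d (−2.93 ± 0.25, at least −2.66), Ccno (−2.47 ± 0.18) and the zinc transporter gene Slc30a3 (−2.20 ± 0.13, at least −1.67). Another Slc30a3 probe, at −0.16, was not called.

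In limma, 2624 of the 12215 genes changed at P0, of which 1227 were higher and 1397 lower. Changes above 1 z unit were mostly falls, with 117 lower and 14 higher. The knockout and wild-type arrays did not overlap for 33.1% of genes, where chance gives 10%. The balance of rises and falls depended on scaling, with 46.8% of calls higher as given, 30.8% on the deposited scores and 14.6% with median scaling, so that a rise at P0 is relative to the array's other genes. With the spread taken from the P0 arrays alone 1345 genes were called, and 1721 without wild-type replicate 2. Median scaling also ended the P0 calls of all 4 endothelial markers (Esam, Cdh5, Emcn and Robo4), of the leukocyte markers Aif1 and Csf1r, and of Npc2, Wdr45, Lamp1, Bok, Col3a1, Ier3, Lpl, Sox9, Stag3 and Fgf9. The deposited scores ended those of Cdh5, Emcn, Robo4, Aif1, Csf1r, Wdr45, Bak1, Col3a1, Stag3 and Fgf9.

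The P7 comparison asks which transcripts differed after a week in which wild-type oocytes enter growth. Every one of the 32 oocyte growth genes fell, with a median of −2.90 (camera adjusted p = 1.23e-37; 32 adjusted over the list alone). Nlrp14, a member of the oocyte NLRP family, differed by −5.47 ± 0.23, Ooep by −4.96 ± 0.31, Gdf9 by −4.77 ± 0.22, Zp3 by −4.40 ± 0.24 and Padi6 by −4.21 ± 0.25. Bmp15 (−3.52 ± 0.16, at least −3.42), Zp1 (−3.17 ± 0.21, at least −3.08) and Mos (−2.50 ± 0.11, at least −2.18) were below background in knockout at both ages. With genes of this kind at their bounds the list median was −2.89. Of the 10 oocyte transcription regulators 8 fell, also adjusted over the list alone (median −0.50, adjusted p = 2.22e-05), with Figla at −1.62 ± 0.16, Sohlh1 at −1.36 ± 0.13 and Nobox at −0.47 ± 0.10, but Sohlh2 did not pass the test (−0.12 ± 0.08, adjusted p = 0.288).

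Genes shared by all germ cells were also lower at P7. Of 21 pan germ cell genes 15 fell and 1 rose, also adjusted over the list alone (median −0.60, adjusted p = 3.85e-08), with adjusted p = 0.0527 with an estimated correlation. Dppa5a (−4.08 ± 0.20), Elavl2 (−2.41 ± 0.16), Tex19.1 (−1.32 ± 0.12), Dazl (−0.87 ± 0.12) and Ddx4 (−0.43 ± 0.09, adjusted p = 0.00253) fell, and Taf7l was the 1 that rose (1.13 ± 0.17). Another Ddx4 probe, at −0.20, was not called. The piRNA pathway genes fell in 16 of 19, also adjusted over the list alone (median −0.49, adjusted p = 7e-09), with Gpat2 at −1.27 ± 0.15. Meiotic prophase genes fell in 11 of 24 and rose in none (12 lower adjusted over the list alone; median −0.23, adjusted p = 0.000226), with adjusted p = 0.245 with an estimated correlation. Smc1b, the meiotic cohesin gene, fell by 1.35 ± 0.13. Primordial germ cell and pluripotency genes fell in 9 of 15 and rose in 2 (10 and 2 adjusted over the list alone; median −0.35, adjusted p = 0.00019), with Sall4 at −2.17 ± 0.12 (at least −1.97) and Ifitm1, which is not confined to germ cells, higher by 1.37 ± 0.13.

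**Figure D2:**
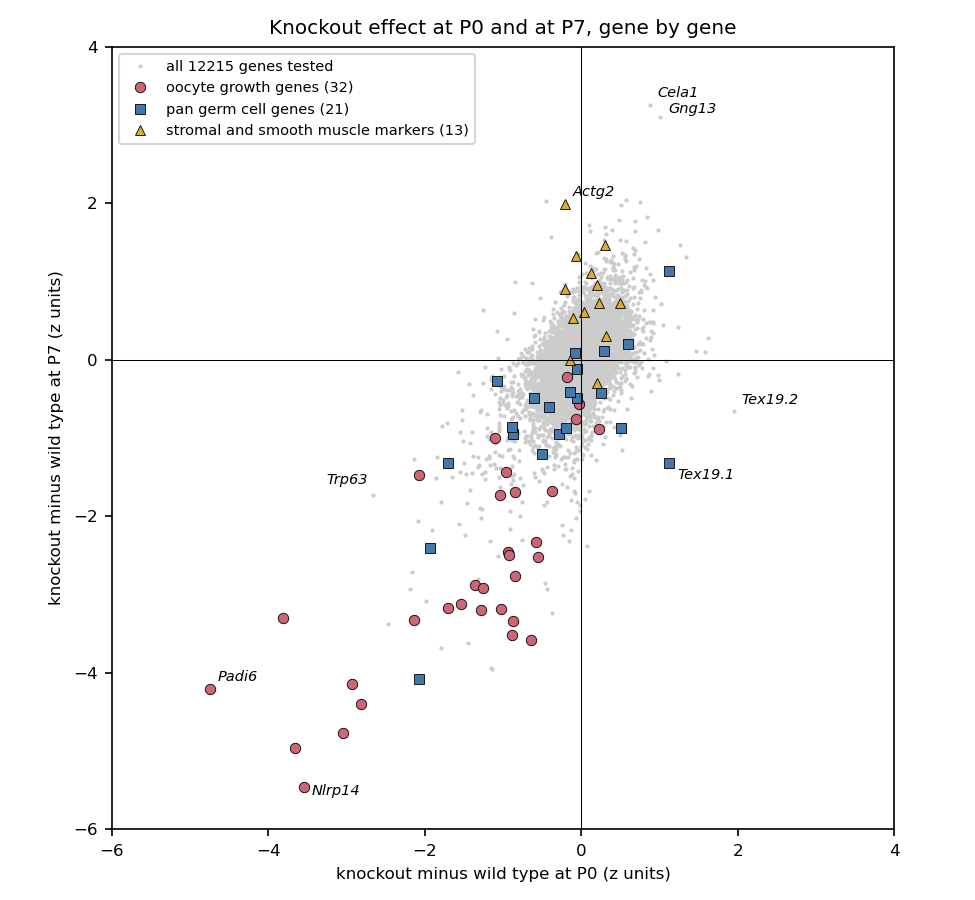
Difference between knockout and wild type at P0 (horizontal axis) and at P7 (vertical axis), in z units, for all 12215 genes tested (grey points), with the 32 oocyte growth genes, 21 pan germ cell genes and 13 stromal and smooth muscle markers in colour. Oocyte growth genes lie low at both ages with medians of −1.04 and −2.90, and Tex19.1 and Tex19.2 lie to the right of 0 at P0 and below 0 at P7.

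Autophagy genes again did not pass the test as a group at P7, whereas lysosome genes rose. Of 36 autophagy genes 8 rose and 4 fell, also adjusted over the list alone (median 0.09, camera adjusted p = 0.505). Map1lc3b rose by 0.37 ± 0.12 (adjusted p = 0.0306) and Vmp1 by 0.42 ± 0.10, Atg5 fell by 0.85 ± 0.11, and Becn1 (−0.03 ± 0.12, adjusted p = 0.881) and Sqstm1 (0.22 ± 0.15, adjusted p = 0.291) did not pass the test. The other Vmp1 probes, at 0.09, 0.06 and −0.06, were not called. The call of Map1lc3b ended on the deposited scores, with quantile normalization within each age, and without knockout replicate 1, knockout replicate 2, wild-type replicate 2 or wild-type replicate 3. Of 31 lysosome genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; median 0.30, adjusted p = 0.000463). Ctsz, a cathepsin gene, rose by 0.72 ± 0.10, the cholesterol transporter gene Npc1 by 0.71 ± 0.10 and Lamp2 by 0.55 ± 0.11, and Lamp1 did not pass the test (−0.14 ± 0.10, adjusted p = 0.329). Of the other Lamp2 probes those at 0.59 and 0.38 were called, and those from 0.14 to 0.22 were not. For Npc1 the other probes at 0.58 and 0.22 were called, and those from 0.10 to 0.13 were not. Lysosome genes are also expressed by macrophages, whose markers were higher at this age.

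None of the 30 DNA break signalling and repair genes rose at P7 and 19 fell (20 adjusted over the list alone; median −0.34, adjusted p = 8.78e-09). Trp63 fell by 1.73 ± 0.15, Rpa1 by 0.95 ± 0.14, Blm by 0.90 ± 0.13 and Rnf168 by 0.74 ± 0.10, and H2ax did not pass the test (−0.27 ± 0.11, adjusted p = 0.0734). The p53 target genes did not pass the test as a list (5 of 26 rose and 3 fell, also adjusted over the list alone; median 0.10, adjusted p = 0.462), although Sesn1 (0.95 ± 0.11), Cdkn1a (0.83 ± 0.13) and Fas (0.44 ± 0.09) rose. Among 28 apoptosis genes 10 rose and 2 fell (11 and 3 adjusted over the list alone, median 0.07, adjusted p = 0.249), including Bbc3 (0.43 ± 0.11) and Bmf (0.62 ± 0.13). A further probe of Sesn1, at 0.16, and of Bbc3, at 0.04, was not called. Cell proliferation genes fell in 21 of 25 and rose in none (22 adjusted over the list alone; median −0.56, adjusted p = 1.25e-12), with Birc5 at −1.38 ± 0.12 and Aurka at −1.24 ± 0.10. PI3K and mTOR signalling genes did not pass the test (1 of 16 rose and 5 fell, also adjusted over the list alone; median −0.08, adjusted p = 0.228), and Kit fell by 1.47 ± 0.18.

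Granulosa cell markers divided at P7. Of 21 markers 11 fell and 6 rose, also adjusted over the list alone (median −0.40, adjusted p = 0.0467), with adjusted p = 0.0945 with an estimated correlation. Those that fell included Amh (−0.88 ± 0.07), which neither genotype expressed above background at P0, Nr5a2 (−1.30 ± 0.09) and the hedgehog ligand gene Dhh (−0.80 ± 0.09), whereas Irx3 rose by 1.25 ± 0.15 and Foxl2 did not pass the test (−0.15 ± 0.09, adjusted p = 0.205). The call on this list was also lost on the deposited scores, with median scaling, a stricter filter, the mean over probes or array weights, with the P7 arrays alone, and without wild-type replicate 1, wild-type replicate 3 or knockout replicate 2. With median scaling its median was −0.02, and with bounds it was −0.28. Among theca and steroidogenic markers 2 of 10 fell and 1 rose, also adjusted over the list alone (median 0.05 but mean −0.10, adjusted p = 0.349), and the 2 that fell, Ptch1 (−1.01 ± 0.14) and Hhip (−0.54 ± 0.08, at least −0.40), are targets of hedgehog signalling.

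Smooth muscle, epithelial and leukocyte markers were higher in P7 knockout ovaries. Stromal and smooth muscle markers rose in 8 of 13 and fell in none (10 and 1 adjusted over the list alone; median 0.73, adjusted p = 0.000226), with Actg2, an actin of smooth muscle, at 2.0 ± 0.25, Myh11 at 1.33 ± 0.17 and Tagln at 0.91 ± 0.14. Surface epithelium and oviduct markers rose in 8 of 11, also adjusted over the list alone (median 0.46, adjusted p = 0.00186), with adjusted p = 0.102 with an estimated correlation, and included Upk1b (1.35 ± 0.21) and Krt18 (0.88 ± 0.12). Macrophage and leukocyte markers rose in 8 of 14 (9 adjusted over the list alone; median 0.27, adjusted p = 0.00347), with adjusted p = 0.124 with an estimated correlation and 0.0560 with median scaling, and included Laptm5 (0.73 ± 0.14) and Fcgr3 (0.47 ± 0.12). Endothelial markers did not pass the test as a list (4 of 12 rose, also adjusted over the list alone; median 0.09, adjusted p = 0.249), nor did testis somatic markers (4 of 11 rose, also adjusted over the list alone; median 0.13, adjusted p = 0.228), erythroid markers (0 of 4 called; median 0.13, adjusted p = 0.689), adipocyte markers (1 of 3 rose, also adjusted over the list alone; median 0.08, adjusted p = 0.281) or immediate early and heat shock genes (4 of 16 rose and 2 fell, or 6 and 2 adjusted over the list alone; median 0.20, adjusted p = 0.249).

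Further large rises at P7, among genes whose arrays did not overlap between genotypes, were in Cela1, an elastase gene (3.26 ± 0.22), Gng13, a G protein subunit gene (3.11 ± 0.18), the interferon-inducible gene Ifi27l2a (2.15 ± 0.17), Mia (2.04 ± 0.19), Wfdc2 (2.01 ± 0.43), Apoc1 (1.98 ± 0.19), Pcp4l1 (1.83 ± 0.14), Ramp1 (1.79 ± 0.13) and Tmem114 (1.78 ± 0.13). Further large falls were in Oas1d (−4.15 ± 0.25), Elobl (−3.94 ± 0.21), Cpsf4l (−3.69 ± 0.14) and Fbxw18 (−3.62 ± 0.18, at least −3.50). In limma 4031 genes changed at P7, 2151 higher and 1880 lower, and changes above 1 z unit numbered 100 higher and 228 lower. The arrays of the genotypes did not overlap for 53.3% of genes, where chance gives 10%. The share of calls that were higher was 53.4%, but 43.2% on the deposited scores and 68.9% with median scaling. The deposited scores ended the P7 calls of Rpa1 (−0.30, adjusted p = 0.203) and Bbc3 (0.32, adjusted p = 0.0546), and of Eif4ebp1, Mcm4 and Sox9. Median scaling ended those of Atg5, Sohlh1, Hsph1, Nusap1 and Uvrag, turned Rpa1 to 0.25 and gave Lamp1 a rise of 0.69 (adjusted p = 0.00881).

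**Figure D3:**
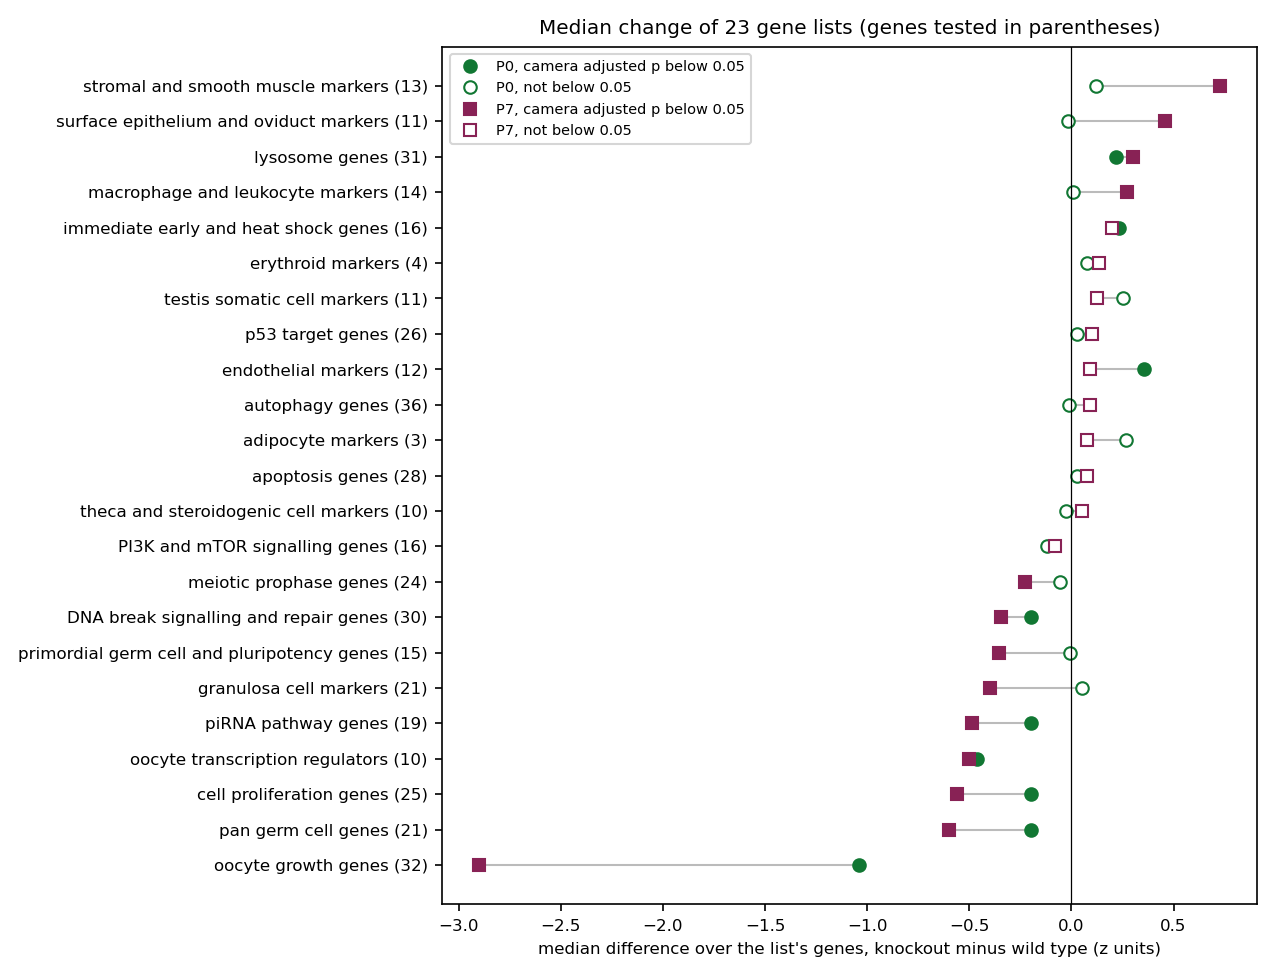
Median difference between knockout and wild type, in z units, over the tested genes of 23 lists (number of genes in parentheses), at P0 (circles) and P7 (squares). Filled symbols have a camera adjusted p below 0.05 at the preset correlation. Oocyte growth genes reach −1.04 at P0 and −2.90 at P7, and stromal and smooth muscle markers reach 0.73 at P7.

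Whether the effect of the knockout itself differed between the ages was tested as an interaction. Age and processing run cannot be told apart, so 1 z unit need not be the same amount of signal at both ages. A difference of unit alone can shift genes that changed the same way at both ages, but would not turn a rise into a fall. Of the 32 oocyte growth genes 25 were called as falling further at P7 than at P0 and none as falling less. Adjusted over the list alone these counts were 26 and 1. The list median was −1.49 (camera adjusted p = 2.79e-20, with adjusted p = 0.0957 with an estimated correlation). Padi6 (−4.75 at P0 and −4.21 at P7), Nlrp5 (−3.81 and −3.30) and Kit (−2.08 and −1.47) lay less low at P7, without a call over all genes. Oosp1 (−2.94 ± 0.26) and Bmp15 (−2.63 ± 0.23) were among the 25 that fell further, and outside the list Khdc1c (−2.86 ± 0.30) and Elobl (−2.79 ± 0.30) shifted as well. In 20 of the 32 a group lay below background. In these 4 genes it was the knockout, at P0 for Elobl and at both ages for Oosp1, Bmp15 and Khdc1c, so that deeper falls would not be seen and the shifts are not exact. The list median was −1.24 over the other 12, of which 8 were called lower and none higher. Tex19.2 shifted by −2.61 ± 0.14, because its P0 rise was replaced by a fall at P7. Dazl (−1.38) and Tex19.1 (−2.45) turned in the same way. Among called genes the largest shifts upward were in Cela1 (2.39 ± 0.31), Actg2 (2.21 ± 0.36), Ifi27l2a (2.17 ± 0.24), Gng13 (2.10 ± 0.26) and Pnliprp1 (1.96 ± 0.51, adjusted p = 0.0213). Trp63, lower at both ages, was lower by less at P7 (0.93, adjusted p = 0.0099).

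In all, the effect in z units differed between the ages for 1587 genes, 872 shifting up and 715 down. The same genes were called lower at both ages in 655 cases, where 215 would be shared by independent lists, and higher at both ages in 466, where 216 would. With median scaling 254 genes were higher at both ages, and without wild-type P0 replicate 2 the number was also lower. Only 25 were higher at P0 and lower at P7 and 55 the reverse. Across genes, which are not independent replicates, the effects at P0 and P7 correlated with r = 0.564 and rho = 0.432, and the comparisons shared no arrays. The count of the interaction was less stable than the others, with 3805 under median scaling, of which 82.0% shifted up, against 54.9%, and 881 to 950 without knockout P7 replicate 1, knockout P7 replicate 2, wild-type P7 replicate 2 or wild-type P7 replicate 3.

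The age comparisons ask how each genotype's ovary changed over the first week. In wild type the oocyte growth genes rose in 26 of 32 and fell in 3 (26 and 4 adjusted over the list alone; median 1.45, P7 minus P0, adjusted p = 6.65e-09), with adjusted p = 0.334 with an estimated correlation. Of this list Oosp1 (2.84 ± 0.18) and Gdf9 (2.58 ± 0.22) rose. Outside it Elobl (3.12 ± 0.21), Khdc1c (3.0 ± 0.21) and Hsd17b1 (2.99 ± 0.23), an estradiol-forming enzyme gene of granulosa cells, rose too. With median scaling the call of Gdf9 ended (0.21, adjusted p = 0.54). In knockout the same list had a median of −0.01 (3 rose and 7 fell, or 3 and 5 adjusted over the list alone; adjusted p = 0.402). These age results depended on scaling: the wild-type call ended on the deposited scores (adjusted p = 0.0614), and the knockout list passed on the deposited scores (median −0.07, adjusted p = 0.0133), within each age (−0.05, adjusted p = 0.0194) and with median scaling (0.14, adjusted p = 0.00572). These medians lay below those of all genes in the same settings (0.171, 0.188 and 0.352). Granulosa cell markers rose in 13 of 21 and fell in 3 in wild type (13 and 4 adjusted over the list alone; median 0.59, adjusted p = 0.00134), with adjusted p = 0.0712 with an estimated correlation. The same markers rose in 11 and fell in 1 in knockout, where the list did not pass the test (median 0.26, adjusted p = 0.0833). Cell proliferation genes rose in 17 of 25 in wild type, also adjusted over the list alone (median 0.50, adjusted p = 5.85e-07), with adjusted p = 0.0712 with an estimated correlation, and had a median of 0.19 in knockout (9 rose and 1 fell, also adjusted over the list alone; adjusted p = 0.27).

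Part of the germ cell genes fell with age in both genotypes. Meiotic prophase genes fell in 13 of 24 in wild type (3 rose; median −0.43, adjusted p = 0.00134, with adjusted p = 0.334 with an estimated correlation and 0.0664 with median scaling, where the median was −0.11) and in 16 in knockout (median −0.53, adjusted p = 2.14e-07, with adjusted p = 0.175 with an estimated correlation). Pan germ cell genes fell in 11 of 21 in wild type (1 rose; median −0.34, adjusted p = 0.00157, with adjusted p = 0.334 with an estimated correlation) and in 16 in knockout (1 rose; median −0.70, adjusted p = 1.15e-08, with adjusted p = 0.124 with an estimated correlation). Taf7l fell by 2.53 ± 0.17 in wild type and by 2.51 ± 0.17 in knockout, and Dazl by 2.64 ± 0.12 in knockout. Syce3 (−2.22 ± 0.14), Pdrg1 (−2.22 ± 0.10, at least −2.06), Gng13 (−2.10 ± 0.18) and Dync1h1 (−1.98 ± 0.15) also fell in wild type. In knockout Pdrg1 (at least −2.50), Tex19.2 (−2.55 ± 0.10) and Id1 (−2.49 ± 0.20) fell, and Actg2 (at least 4.23), Pnliprp1 (3.41 ± 0.36), Sspn (2.22 ± 0.66), Ifi27l2a (2.17 ± 0.17) and Ogn (2.14 ± 0.13) rose. Stromal and smooth muscle markers rose in 8 of 13 and fell in 1 in knockout, also adjusted over the list alone (median 1.04, adjusted p = 0.00521), with adjusted p = 0.124 with an estimated correlation. That call also ended on the deposited scores (adjusted p = 0.279), with quantile normalization within each age (0.591) and with median scaling (0.703).

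In limma 6091 genes changed with age in wild type (3058 higher, 3033 lower) and 6049 in knockout (3403 higher, 2646 lower). The P0 and P7 scores were deposited with different numbers of decimals, and age and processing run cannot be told apart, so these counts hold any difference between runs. Median scaling raised the share of higher calls from 50.2% to 71.7% in wild type and from 56.3% to 86.8% in knockout, and with it the wild-type rises of the oocyte growth, granulosa and proliferation lists did not pass the test. The granulosa list did not pass on the deposited scores (adjusted p = 0.0796) or within each age (0.0762) either.

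Genes beside Lhx8 on its chromosome were counted apart, because a knockout allele on a mixed background can carry linked variants of its strain of origin. Within 5 Mb of Lhx8, 24 genes were tested. At P0 1 of them changed, Zranb2, or 4.17% against 21.5% of all other genes (two-sided Fisher exact p = 0.0432). At P7 8 changed, or 33.3% against 33.0% (exact p = 1): Acadm, Asb17os, Gipc2, Lrrc40, Msh4, Negr1, Pigk and St6galnac5. These genes are named because the counts are small, and Zranb2 was named after its value was seen.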

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

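Median scaling and the median over genes above background in every group were tests chosen after the results were seen, and the expected outcomes of the split counts, first written the wrong way round, were reworded after the counts were known.

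Lower oocyte growth genes in P0 knockout ovaries were weighed against a loss of germ cells and a weaker signal. Only genes well above background in wild type were used. The median of 17 pan germ cell genes was −0.41 (4 called higher, 8 lower), and that of 21 oocyte growth genes −1.54. The difference of medians was 1.13 (permutation p = 0.0043, with genes shuffled as if independent). Fewer germ cells would lower both lists alike only on a log scale and without somatic signal. Whether a log was taken is unknown and the lists were not matched on level, so the gap alone does not decide. Fewer germ cells alone would not give the 4 called higher, although a rise at P0 is relative to the array's other genes. Of 10000 random lists matched on wild-type level 0% had a median as low (lowest −0.21). Quantile normalization holds such lists near no change, so this shows a fall beyond that of genes of like level. It argues only against a weaker signal that genes of a level share. Some loss of germ cells stays open, and so does lower expression per oocyte, which may explain the pattern.

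Lower germ cell genes in P7 knockout ovaries were weighed in the same way. Of 66 oocyte growth, pan germ cell and meiotic genes well above background in wild type, 93.9% were lower, with medians of −2.90 (32 of 32 lower), −0.86 (16 of 18) and −0.45 (14 of 16). The set leaves out genes dim in wild type, among them Taf7l, which rose by 1.13 and which fewer germ cells would not raise, and it holds 4 genes that were not lower, Dnd1, Hspa2, Rec8 and Mlh3. Of 10000 matched random lists 0% had a median as low as that of the 77 pooled genes (−0.87, lowest random −0.13). After quantile normalization this again argues only against a weaker signal that genes of a level share. Fewer germ cells stay open as a source of these falls. Lower expression per cell would also give falls in each list, so the test cannot tell these causes apart. The gap between the list medians was not tested at P7.

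Somatic markers at P7 were weighed against a larger share of somatic RNA as germ cells are lost. That share would raise all somatic types, and by like amounts only if a log was taken before scoring. The medians were −0.40 for granulosa, 0.73 for stromal and smooth muscle, 0.09 for endothelial and 0.27 for leukocyte markers. For no difference the permutation p was 0.00068, with genes shuffled as if independent, although markers of a cell type can move together. The granulosa markers, of which 11 of 21 fell and 6 rose, argue against the share as the whole cause. The call of their list depended on the settings. A change in the somatic types themselves stays open and may add to the share.

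Other splits of the arrays were counted for each comparison. With 6 arrays there are 10 splits, too few for a share under 0.05: the real split, the 1 with as many genes, called 2624 at P0 (highest other 5), 4031 at P7 (0), 6091 with age in wild type (1) and 6049 with age in knockout (1). For the interaction 4 of 100 splits, the real one included, called at least its 1587 genes, and the highest other called 2691. That share is under 0.05, but all 3 other splits this large kept the P7 arrays grouped by genotype, as did 10 splits in all, and so 4 of those 10 called as many. The 9 others of that kind called 631 to 2691 genes and the 90 remaining splits at most 46, which points to the P7 genotype groups. Mirrored splits were counted once within each age, so splits with genotype labels swapped at 1 age only were not run. The share of 4 in 100 is therefore not that of all splits. The counts do not exclude chance, and they do not show that the effect differed between the ages beyond what the P7 effect alone gives.

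The effect of the knockout in z units differed between P0 and P7, by the interaction, for 10 of 23 lists. Age and processing run cannot be told apart, so a difference of unit between the runs may be part of this. The medians of P7 minus P0 were −1.49 for oocyte growth genes (adjusted p = 2.79e-20), −0.25 for pan germ cell (adjusted p = 0.000569), −0.22 for meiotic prophase (adjusted p = 0.00386), −0.44 for primordial germ cell and pluripotency (adjusted p = 0.0126), −0.21 for DNA break (adjusted p = 0.0189), −0.19 for piRNA (adjusted p = 0.0189) and −0.34 for proliferation genes (adjusted p = 3.82e-06). They were −0.45 for granulosa (adjusted p = 0.00737), 0.65 for stromal and smooth muscle (adjusted p = 0.00265) and 0.44 for surface epithelium and oviduct markers (adjusted p = 0.00468). For oocyte growth genes the median was −1.24 over the 12 with an array above background in every group. With an estimated correlation none of the 10 passed (adjusted p from 0.0775 to 0.38). The piRNA call also ended without wild-type P0 replicate 1 (adjusted p = 0.0867), wild-type P7 replicate 2 (0.0899) or wild-type P7 replicate 3 (0.0543), and the DNA break call without wild-type P0 replicate 1 (0.0893). With median scaling, where the median of all genes was 0.212 against 0.0232 as given, the medians of DNA break (0.04, adjusted p = 0.0778), proliferation (0.14, adjusted p = 0.537) and granulosa lists (0.02, adjusted p = 0.0132) lay above 0, and the surface epithelium list did not pass (0.75, adjusted p = 0.0806).

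The effect in z units also differed between the ages for 75 of 156 genes named here, each with an adjusted p below 0.05. For 24 of them, Bak1, Actg2, Tagln, Trp63, Fas, Cyp11b2, Gipc2, Msh4, Pdrg1, Hhip, Slc30a3, Amh, Oas1d, Sall4, Zp1, Radx, Mos, Zp3, Cpsf4l, Fbxw18, Bmp15, Elobl, Khdc1c and Oosp1, at least 1 group had no array above background, so the value is not exact. It was higher at P7 for Cela1 2.39, Actg2 2.21, Ifi27l2a 2.17, Gng13 2.10, Pnliprp1 1.96, Mia 1.47, Apoc1 1.47, Myh11 1.40, Upk1b 1.39, Ramp1 1.32, Tagln 1.11, Tmem114 1.09, Pcp4l1 0.99, Krt18 0.96, Dync1h1 0.93, Trp63 0.93, Irx3 0.88, Ifitm1 0.84, Atp6v1b2 0.81, Bmf 0.67, Rnf8 0.63, Ifi35 0.59, Mcoln1 0.54, Fas 0.53, Acadm 0.42, Cyp11b2 0.34 and Bak1 0.30. It was lower at P7 for Gipc2 −0.30, Msh4 −0.44, Pdrg1 −0.48, Rnf168 −0.50, Hhip −0.56, Spo11 −0.58, Blm −0.59, Nusap1 −0.63, Lpl −0.64, Ddx4 −0.68, Slc30a3 −0.74, Mcm4 −0.75, Dhh −0.79, Pfkl −0.81, Ptch1 −0.82, Ccno −0.90, Aurka −0.91, Amh −0.92, Smc1b −1.0, Atg5 −1.0, Dusp1 −1.05, Sohlh1 −1.07, Hsd17b1 −1.08, Id1 −1.18, Gpat2 −1.2, Nr5a2 −1.21, Oas1d −1.22, Hsph1 −1.24 and Sall4 −1.25. Larger negative differences were those of Gadd45g −1.34, H1f2 −1.35, Dazl −1.38, Fabp3 −1.42, Zp1 −1.46, Radx −1.47, Mos −1.57, Zp3 −1.58, Gdf9 −1.72, Cpsf4l −1.90, Nlrp14 −1.92, Dppa5a −2.0, Fbxw18 −2.17, Tex19.1 −2.45, Tex19.2 −2.61, Bmp15 −2.63, Elobl −2.79, Khdc1c −2.86 and Oosp1 −2.94.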

How the results depend on the processing

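Quantile normalization within each age, median scaling, the stricter filter and the minimum difference of 0.5 were the tests chosen after the data were seen. Named genes mostly held their call and direction: over the settings other than leave-one-out, 982 gene results at P0 were the same and 69 lost the call, and at P7 1186 were the same, 19 lost it, 8 gained it and 5 reversed. For lists the numbers were 262 the same and 13 lost at P0, with 1 gained, and 263 and 13 at P7. Median scaling reversed Eif4ebp1 (0.26), Lamp1 (0.69), Mcm4 (0.27) and Rpa1 (0.25) at P7, and no filter reversed Hspa1b (0.0605); the cause was not tested. It also raised the interaction count to 3805. Of the calls, 64.6% at P0 and 79.6% at P7 kept direction and call on the deposited scores, 60.3% and 78.7% with median scaling, and 83.2% and 87.6% with normalization within each age. The median of all genes in the age comparisons (wild type, knockout) was 0.00693 and 0.0392 as given, 0.158 and 0.171 on the deposited scores, 0.170 and 0.352 with median scaling and 0.142 and 0.188 within ages.

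Stricter thresholds call fewer genes by construction: an adjusted p under 0.01 gave 1106 at P0, 2514 at P7 and 554 for the interaction, and a minimum of 0.5 gave 813, 1656, 2211 (age, wild type) and 2380 (age, knockout). With the arrays of 1 age alone, and so with the spread of that age only, 1345 were called at P0 and 5148 at P7. The fit with 1 spread shared by both ages called more at P0 (2624) and fewer at P7 (4031). How far the spread and how far the fewer degrees of freedom made this difference was not tested. Leaving out 1 array gave 1721 (without wild-type P0 replicate 2) to 2596 at P0, 2886 to 3237 at P7, 4790 to 5554 and 4939 to 5797 with age, and 881 to 1762 for the interaction, where the cause of the low values was not tested. The replicate block gave 2472 at P0, 3974 at P7, 1484 for the interaction, 5995 and 5993 with age, and ended the granulosa call at P7 (adjusted p = 0.0641). Arrays of 1 replicate number correlated with r = −0.00549, −0.0250 and −0.0290 at P0 and −0.136, 0.142 and −0.101 at P7 after group means were removed. These values gave no clear sign that the numbers pair samples, but so few pairs cannot exclude it. With an estimated correlation the P0 calls of the DNA break (−0.20, adjusted p = 0.194), lysosome (0.22, adjusted p = 0.194) and oocyte growth lists (−1.04, adjusted p = 0.145) ended because that test allows for genes moving together. With the mean over probes the lysosome median was 0.14 (adjusted p = 0.0756, cause not tested), and without single arrays 0.156 to 0.255. Genes higher at both ages numbered 254 with median scaling and 252 without wild-type P0 replicate 2. Within 2 Mb of Lhx8, 0% of genes changed at P0, in a smaller window. Signal over background limits dim genes, since 30.2% of probes in knockout and 35.1% in wild type lay above it at P0. Not run were normalization and median scaling of bead signals after control-probe correction, a signal floor, a detection p filter, a BeadChip block and a 2-fold threshold, which need values not used here.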

Other observations

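Both tests in this part were chosen after the rises of Cma1, Cpa3 and Ifi27l2a were seen, and so were the 2 lists of genes, which were written before the values of their other members were examined.

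The mast cell protease genes Cma1 and Cpa3 rose in P0 knockout ovaries, from means of 1.0 and 1.02 to 2.34 and 2.28, which may come from more mast cell RNA. The rise was carried by 2 of 3 animals: Cma1 was 3.24, 2.56 and 1.21 in knockout (highest wild type 1.16) and Cpa3 3.10, 2.60 and 1.13 (highest wild type 1.11). Of 9 listed markers other than these, 5 passed the filter and were tested: Tpsb2 (0.88), Tpsab1 (0.68), Mcpt4 (0.81), Fcer1a (0.03) and Hdc (0.83). Their median was 0.811, and 0% of 10000 matched random lists had one as high, a share that treats the markers as independent genes. These too varied between animals, as Mcpt4 was 1.98, 0.583 and 0.0717 and Hdc 3.04, 2.83 and 2.19 in knockout (highest wild type 0.179 and 2.23). Tpsab1 was 4.01, 0.892 and 2.57 in knockout against 1.98, 1.63 and 1.83 in wild type. In knockout replicate 2 it thus lay below every wild-type animal. Each of the 5 markers was highest in knockout replicate 1, so their median leans on that animal. None was called by itself at P0 in limma (adjusted p from 0.0511 to 0.823), where 4336 of all genes had an unadjusted p under 0.05. At P7 Tpsb2 (1.10), Mcpt4 (1.51) and Hdc (1.17) were called higher. None of these markers belongs to a list fixed before, and no sort that would remove mast cells is described.

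A general interferon response was tested because Ifi27l2a rose at P7. Of 16 listed interferon-stimulated genes 9 were tested, with a median of 0.200, and 4.32% of 10000 matched random lists had one as high, short of the highest 2.5% that the test asked for. Ifit3 (0.39), Irf9 (0.30), Usp18 (0.19) and Ifi35 (0.43) were called higher and none lower. A median inside the central 95% of random lists had been set to exclude a general response, but so narrow a miss excludes nothing, and with 9 genes the explanation stays open. None of the 16 belongs to a list fixed before.

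Gng13, singled out after its values were seen, had mean scores of 2.89 in wild type and 3.90 in knockout at P0, and 0.785 and 3.89 at P7.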
